A study of Mus musculus with 2 samples.

How the data were processed

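DNase-seq was done on the gastrocnemius of 2 male B6CASTF1/J mice aged 36 days, each with 1 library. Per the labels, the animals are separate biological replicates of 1 group, and no other group was compared. Nuclei were isolated from tissue, so signal comes from the nuclei of all cell types present. Per the labels, the files use the mm10 assembly, which is GRCm38. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. One parent of these hybrids is CAST/EiJ, and how reads of its alleles were aligned to the reference is not given in those sources either.

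The authors deposited for each library a pair of peak lists in which each peak carries a signal value, the height of its cleavage density. Within a library all peak signal values were whole multiples of a step, 0.0123 in replicate 1 and 0.00657 in replicate 2 (100% of distinct values within 0.05 of a step), as when counts are divided by a depth, but the authors' scaling is not stated. The depth in reads is unknown. If the step is what 1 cleavage is worth, replicate 2 was 1.88 times deeper, and the median peak of the shorter lists was 143 steps high in replicate 1 and 202 in replicate 2. The authors also deposited a table of false discovery rates (q-values) per run of bases, which lists runs below 0.05. Each peak of the shorter list held a base with a q-value at or below 0.001 in the same library, and each of the longer list a base at or below 0.05. Peaks were called per library and not pooled, per the deposited file listing. The shorter lists were the main ones. The longer lists held 83409 and 83736 peaks. In the shorter lists, 181 neighbouring peaks overlapped in replicate 1 and 1392 in replicate 2. The deposited footprint lists carry a score that is 0.01 on every line, so it ranks nothing, and footprints were used by position only. They were 7 to 73 bp wide in replicate 1 and 7 to 87 bp in replicate 2, and covered 1.92 Mb and 2.96 Mb.

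The reference was GRCm38.p6 with GENCODE release 21 of the mouse annotation. Start sites (TSSs) were taken from protein-coding transcripts of the basic set, which gave 41408 sites of 21851 genes. A gene had a promoter peak in a library if a peak lay within 500 bp of one of its TSSs, and its value was that of the highest such peak. A promoter peak in both libraries did not require that the peaks overlap. Replicated regions were merged regions of both shorter lists that held a peak of each library. Distal regions lay over 1 kb from all 132629 annotated TSSs and were counted within the gene body and 10 kb either side. Nearby genes can share a promoter peak or a distal region, and overlapping gene models cannot be told apart by position. Regions were placed in the classes promoter, exon, intron and intergenic, in that order.

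Shared peaks, location classes and footprints were set against 100 circular shifts of each list within its chromosome, leaving out the assembly gap of 3 Mb at the start. Promoter peaks of 30 gene lists (337 entries, each matched to a gene) were tested with Fisher's exact test, two-sided, against all other protein-coding genes. Distal regions of the lists were set against 10000 random lists matched on gene length decile, with a two-sided permutation p whose smallest possible value is 2.0e-04. P-values were adjusted by Benjamini-Hochberg over the 30 lists. The lists cover muscle (fast-fibre, slow-fibre, shared sarcomere, excitation-contraction, glycolysis and glycogen, oxidative metabolism, regulators of muscle identity, developmental contractile and neuromuscular junction genes), other cells of muscle (satellite cells, fibro-adipogenic progenitors, tenocytes, endothelium, smooth muscle and pericytes, macrophages, lymphocytes, erythroid cells, adipocytes and Schwann cells), other tissues (liver, neuron, germ cell, keratinocyte and heart), housekeeping genes, hindlimb and anterior Hox genes, and circadian, atrophy and stress, and immediate early genes. Heart and muscle share part of their genes, as do several of the other lists. For motifs, 21 consensus sequences were searched on both strands in 30 bp windows centred on footprints that lay in peaks, against windows of the same size placed outside footprints in the same peaks, by Fisher's exact test, two-sided, adjusted over the 21 motifs. Control windows were placed at random in the rest of the peak and may lie nearer its edges than footprints do. Distances to the edges were not measured. Exact Clopper-Pearson 95% intervals cover counting error only. No promoter peak means none at the authors' threshold, at a depth that is unknown.

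Named genes followed a rule. In each list these were up to 4 members with a promoter peak in both libraries that had the highest promoter value, by the lower of both within-library percentiles, and up to 2 members without a promoter peak in either library, in alphabetical order. Genome-wide they were the 10 genes with the highest promoter percentile and the 10 with the most replicated distal regions within the gene body and 10 kb either side. Some genes that this rule names, and 1 motif, are not reported here. Any other gene was chosen after its values were seen, as were the myosin heavy chain cluster, the Hox clusters, gene families, packed windows and the comparison of promoters open in a single library.

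The design, the tests, the gene lists, the motifs, the rule for named genes and most alternatives were fixed before the data were examined. Alternatives were a reciprocal overlap of 50%, peaks at or above the median value of their list, equal numbers of top peaks, the longer lists, promoter windows of 1000 and 100 bp, distal regions within 50 kb, random lists matched on the decile of promoter CpG content, footprints with at least 50% of their length inside a peak, footprints as called, peaks over 1 kb from a TSS, and each replicate alone. Alternatives chosen after seeing the data were TSSs of all annotated transcripts, the longer lists for distal regions and for footprints in peaks, and footprints inside replicated regions. Ranking footprints by the authors' value was planned but not run, since that value is constant.

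The steps were tested on simulated data. With 0, 30 and 70% of 50760 peaks implanted as shared, 0.778, 30.6 and 70.2% were recovered, and implanted correlations of 0, 0.5 and 0.9 gave a rho of 0.0024, 0.478 and 0.890. Of 600 changed gene lists drawn among 21851 genes 97.3% were called in the right direction, 0.417% of 2400 unchanged lists were called, and 0% of 100 runs without a changed list gave a call. The changed lists were the largest ones and were set almost fully open or almost fully closed. Power for smaller shifts or smaller lists was not simulated. The random-list step recovered 5 of 5 raised lists and called 0 of 15 others. Its raised lists had several times the mean of other genes, and p-values were adjusted over fewer lists than 30. Smaller rises were not simulated. A motif implanted in 10% of 19998 windows was found in 10.0%, against 0.0050% of controls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.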

Results

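Open chromatin was mapped by DNase-seq in the gastrocnemius, the large calf muscle, of 2 male mice aged 36 days. DNase-seq cuts accessible DNA in isolated nuclei with DNase I, and dense cleavage marks open promoters, enhancers and other regulatory sites. The animals were B6CASTF1/J hybrids, the offspring of a cross between the C57BL/6J and CAST/EiJ strains. They formed 1 group with 1 library each, named replicate 1 and replicate 2 here. No treated, younger or other-tissue group was compared, so the questions asked were which regions were open in both animals, which genes and sequence motifs they held, and how far the animals differed. Replicate 1 had 50760 peaks of open chromatin (median width 180 bp) that covered 9.07 Mb, and replicate 2 had 49230 (median 201 bp) that covered 11.2 Mb. The value of each peak, the authors' signal height, had a median of 1.76 in replicate 1 and 1.33 in replicate 2, and values were ranked within a library only. All positions are on mm10. With 2 animals, p-values below come from tests over genes or sites and describe these libraries, not muscle in general.

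Strong open regions recurred in both animals and weak ones often did not. Of the replicate 1 peaks, 68.0% overlapped a replicate 2 peak by at least 1 bp (95% interval 67.6 to 68.4), and 68.3% of the replicate 2 peaks overlapped a replicate 1 peak (67.9 to 68.7). Lists shifted along each chromosome overlapped by a mean of 0.815% and 0.851% and by at most 0.928% and 1.00% in 100 shifts. With each list split into 5 equal parts by value, 33.7% of the weakest part of replicate 1 recurred, against 98.4% of its strongest part. For replicate 2 these shares were 12.9% and 99.2%. Merging both lists gave 63849 regions, of which 32662 (51.2%) were open in both animals, 16230 in replicate 1 alone and 14957 in replicate 2 alone. Across the 34504 replicate 1 peaks with a partner, which are not independent replicates, the values of both libraries had a Spearman's rho of 0.85.

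The replicated regions were rich in promoters. Within 500 bp of a transcription start site lay 47.1% of regions found in both animals, against 17.8% of those in replicate 1 alone and 26.0% of those in replicate 2 alone. Regions over 1 kb from any start site made up 48.6%, 77.5% and 65.0% of these sets. Requiring a reciprocal overlap of 50% left 50.2% of replicate 1 peaks and 51.8% of replicate 2 peaks as shared. Intervals are exact (Clopper-Pearson) and cover counting error only, not the spread between animals.

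**Figure D1:**
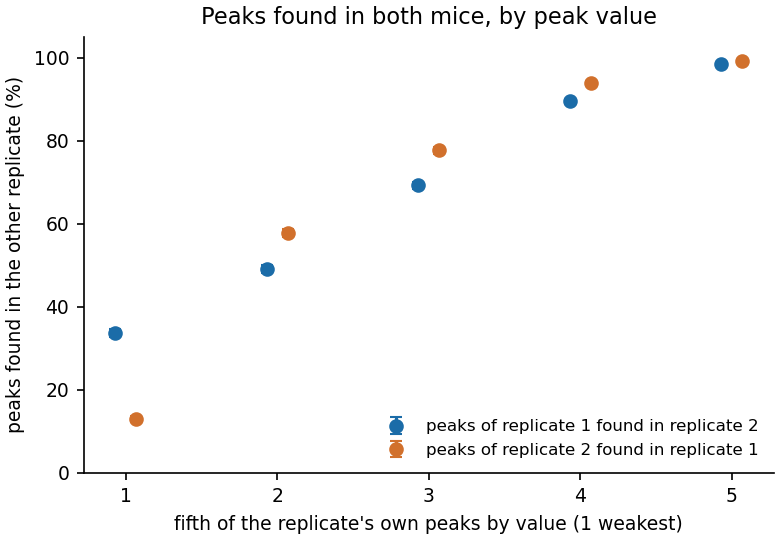
Percent of peaks that overlapped a peak of the other replicate by at least 1 bp (vertical axis) against the fifth of the replicate's own peaks by deposited value, 1 being the weakest (horizontal axis), with bars for the exact 95% interval. Replicate 1 ran from 33.7% to 98.4% and replicate 2 from 12.9% to 99.2%.

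Promoters were open in both animals at 11849 of 21851 protein-coding genes, or 54.2% (95% interval 53.6 to 54.9). A further 348 genes had a promoter peak in replicate 1 alone and 629 in replicate 2 alone. List members named for a peak in a single library were chosen after their values were seen. The strongest promoter of the genome by its lower within-library percentile was that of Dynlt1b, a dynein light chain gene on chromosome 17 (6430112 to 6436296), with values of 42.3 and 32.4. Next came Hjurp, the histone chaperone that loads the centromeric histone, at 36.5 and 21.5, and Fbh1, a DNA helicase gene, at 25.1 and 15.3. Add3 (adducin), Nup107 (a nuclear pore protein), Glo1 (glyoxalase), Hnrnpc (an RNA-binding protein), Bahcc1, Tle4 (a transcriptional corepressor) and Ing2 (a chromatin reader) completed the top 10, with replicate 1 values from 20.8 to 31.6 and replicate 2 values from 13.9 to 15.4. None of these 10 genes belongs to a muscle list.

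Genes of sugar breakdown were the muscle list that stood apart from other genes. A promoter peak in both animals was found at 12 of 13 glycolysis and glycogen genes, 92.3%. The strongest was at Gys1, the muscle glycogen synthase, on chromosome 7 (gene at 45434844 to 45456619, peaks at 45434641 to 45434860 and 45434621 to 45434880), with values of 22.4 and 11.1. Promoter values were 9.78 and 5.49 at Pkm (pyruvate kinase), 9.51 and 5.38 at Ldha (lactate dehydrogenase A) and 7.85 and 4.75 at Tpi1 (triosephosphate isomerase). Eno3, the muscle enolase, was the member without one in both, with a peak in replicate 2 alone. The list exceeded other protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 30 lists, p = 0.0134). Against 10000 random lists of the same promoter CpG content, which averaged 55.6%, the two-sided permutation p was 2.0e-04, the smallest that these permutations can give, and the adjusted permutation p was 0.0020.

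Oxidative metabolism genes had promoter peaks in both animals at 11 of 14 members, 78.6%, which did not pass against all other genes (adjusted exact p = 0.196). Among them were Esrra, an orphan nuclear receptor that drives mitochondrial genes (21.9 and 11.4), Slc25a4, the muscle adenine nucleotide carrier (14.1 and 7.09), Cs, citrate synthase (11.3 and 6.31), and Ndufs1, a complex I subunit (11.3 and 5.63). Mb, which encodes myoglobin, had no promoter peak in either library but had 2 replicated distal regions within its body and 10 kb either side. Against random lists of the same CpG content, which averaged 47.8%, the list did pass (adjusted permutation p = 0.021). With peaks at or above the median value of their list, the share was 50%, close to the 47.5% of other genes (adjusted exact p = 1). Random lists matched on CpG content were not drawn for that setting, so whether their call would hold there is not known.

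Contractile genes, the most muscle-specific lists, did not have promoter peaks more often than other genes. Fast-fibre genes had them in both animals at 5 of 13 members (38.5%, adjusted exact p = 0.439), slow-fibre genes at 4 of 11 (36.4%, 0.547 by the same exact test) and genes of the sarcomere shared by fibre types at 9 of 20 (45%, 0.677, exact). Mylpf, the fast regulatory light chain (ENSMUSG00000030672.12, chromosome 7, 127208890 to 127214298), had values of 6.51 and 3.39. These come from peaks that do not overlap, at 127208561 to 127209060 in replicate 1 and 127209241 to 127209460 in replicate 2. Actn3, the fast alpha-actinin, had 2.86 and 1.94, Mybpc2, the fast myosin-binding protein C, 3.06 and 1.87, and Tnni2, the fast troponin I, 3.21 and 1.80. In the slow-fibre list, Atp2a2, the slow calcium pump, had 5.59 and 3.73, Tpm3 (a tropomyosin gene) 6.81 and 3.38, Actn2 3.76 and 1.62 and Casq2 (calsequestrin) 1.59 and 1.08. Myh7 and Myh7b, both slow-type myosin heavy chains, had none. The shared sarcomere genes with the strongest promoters were Tpm1 (tropomyosin, 14.6 and 7.35), Cryab (a small heat shock protein, 8.61 and 3.17), Ckm (muscle creatine kinase, 6.45 and 3.37) and Des (desmin, 6.21 and 3.11). The peaks of Tpm3, Tpm1, Cryab and Ckm lay at annotated start sites inside the gene span, and transcript forms were not told apart. Lmod2 and Mybpc1 had no promoter peak in either library. Against random lists of the same CpG content the direction turned: the fast-fibre and shared sarcomere shares lay above means of 23.9% and 30.2%, as did the slow-fibre share above its own, and none passed (adjusted permutation p = 0.53, 0.38 and 0.84). Without replicate 2 the shared sarcomere share was 60%, above the 55.8% of other genes (adjusted exact p = 0.988).

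Fast-fibre promoters were called more often in replicate 1, by a split that did not pass the adjusted test. Myl1, Tnnt3, Tnnc2, Pvalb and Casq1, which encode a fast light chain, both fast troponin subunits T and C, parvalbumin and the fast calsequestrin, had promoter peaks in replicate 1 alone. No fast-fibre gene had one in replicate 2 alone. Replicate 1 alone would thus give 10 of 13 members and replicate 2 alone 5 of 13. Set against the 348 and 629 genes of single-library promoters genome-wide, this split of 5 to 0 had an unadjusted exact p of 0.0056 but an adjusted exact p of 0.169 over 30 lists. That comparison was chosen after the values were seen.

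At the cluster of skeletal myosin heavy chain genes on chromosome 11, Myh2 (67171027 to 67197517) and Myh1 (67200052 to 67224575), the fast IIa and IIx myosins, had no promoter peak in either library. Nor did Myh4 (67238029 to 67260446), the IIb myosin, chosen after its values were seen; the longer peak lists held a weak promoter peak for it in both libraries, with values of 0.740 and 0.723. Replicated regions instead lay in the intergenic stretch between Myh3, the embryonic myosin, and Myh2. The strongest, at 67120781 to 67121060, had values of 4.32 and 1.89. Others lay at 67112101 to 67112300 (2.24 and 1.68), 67112875 to 67113060 (1.52 and 1.93) and 67153302 to 67153460 (1.86 and 1.06). A further replicated region at 67350501 to 67350700 lay inside Myh13 (0.999 and 2.09). These regions were also chosen after their values were seen, and no test was run on them.

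**Figure D2:**
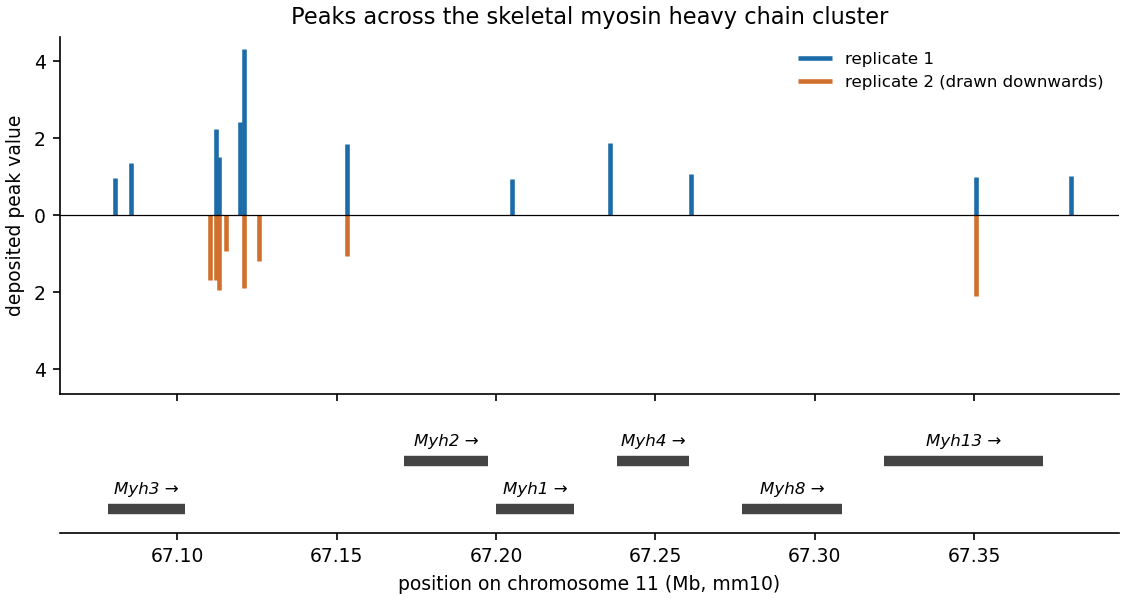
Deposited peak value (vertical axis, replicate 2 drawn downwards) against position in Mb on chromosome 11 of mm10 (horizontal axis) over the skeletal myosin heavy chain genes, drawn as bars with arrows for their strand. Peaks of both replicates coincide between Myh3 and Myh2, the strongest with values of 4.32 and 1.89, and no peak stands at the starts of Myh2, Myh1 or Myh4.

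Excitation-contraction coupling genes had promoter peaks in both animals at 8 of 13 members (61.5%, adjusted exact p = 0.838). They included Asph (11.1 and 5.60), whose locus also encodes junctin, Bin1, which shapes transverse tubules (9.38 and 3.92), Jph1 (junctophilin, 5.86 and 2.75) and Ryr1, the calcium release channel (3.26 and 1.72). Scn4a, the muscle sodium channel, and Trdn (triadin) had none. With peaks at or above the median value of their list the direction turned, at 38.5% against 47.5% of other genes (adjusted exact p = 0.65). Random lists of the same CpG content averaged 35.3% (adjusted permutation p = 0.085). At neuromuscular junction genes 5 of 11 had one (45.5%, 0.677 by the exact test). Etv5, a transcription factor of synaptic nuclei, had values of 15.1 and 7.89 and Chrnb1, a subunit of the acetylcholine receptor, 8.69 and 3.63, with lower values at Rapsn (2.22 and 1.41) and Dok7 (1.87 and 1.30). The Dok7 values come from peaks that do not overlap between the libraries. Ache and Chrna1, the esterase and another receptor subunit, had no promoter peak in either library. The junction share was 27.3% at or above the median value and 63.6%, above other genes, without replicate 2 (adjusted exact p = 0.39 and 0.96). Genes of developing contractile tissue had 2 of 7 (28.6%, 0.431, exact): Myl4, an embryonic and atrial light chain, at 10.9 and 15.3, and Ncam1, an adhesion molecule, at 2.69 and 2.14. Actc1 (cardiac actin) and Chrng (the fetal receptor subunit) had none.

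Regulators of muscle identity had promoter peaks in both animals at 12 of 15 genes (80.0%, adjusted exact p = 0.133). Mef2a (11.2 and 7.81), Tead1 (8.25 and 6.09), Mef2d (8.43 and 5.47) and Srf (9.69 and 4.46), transcription factors of muscle genes, led the list. Myf5, Myf6 and Myog, members of the MyoD family, had a promoter peak in replicate 2 alone. Without replicate 1, therefore, 15 of 15 genes had a peak and the list passed (adjusted exact p = 0.0043). Random lists of the same CpG content averaged 73.2% (adjusted permutation p = 0.96 against the share in both animals).

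Promoters of daily rhythm, early response and housekeeping genes were open at nearly every member. All 12 circadian clock genes had a promoter peak in both animals (adjusted exact p = 0.00437). Tef, a clock output factor, had values of 21.3 and 10.7, the repressor gene Nr1d1 had 16.1 and 10.4, its relative Nr1d2 had 16.1 and 8.57, and Per3, a period gene, 15.4 and 8.22. All 9 immediate early genes had one too (adjusted exact p = 0.0134), led by Jun (16.9 and 11.5), Egr1 (13.8 and 9.32), Atf3 (13.7 and 7.60) and Junb (9.73 and 6.36). So did 14 of 14 housekeeping genes (adjusted exact p = 0.00155), among them Rplp0, a ribosomal protein (16.2 and 16.3), Ppia (12.5 and 11.5), Ywhaz (12.2 and 7.87) and Polr2a, the large subunit of RNA polymerase II (11.8 and 9.37). Of the atrophy and stress genes 8 of 9 had one (88.9%, adjusted exact p = 0.0966), including the glucocorticoid target Fkbp5 (14.0 and 7.87), Gadd45a (9.23 and 5.57), Foxo1 (5.33 and 4.34) and Cdkn1a (5.14 and 3.88). Mstn, which encodes myostatin, had none. Among random lists of the same CpG content, which averaged 83.5%, 88.0% and 85.5%, the circadian, immediate early and housekeeping calls were lost (adjusted permutation p = 0.38, 0.92 and 0.47). More than 2.5% of those lists reached 100% too, so that comparison could not have called these lists higher. With peaks at or above the median value of their list, the atrophy and stress list passed (adjusted exact p = 0.041).

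Promoters of blood cells were closed at this threshold. None of 12 macrophage and myeloid genes (adjusted exact p = 0.00126), 8 lymphocyte genes (0.00643, exact) or 9 erythroid genes (0.00440, exact) had a promoter peak in both animals, each below other genes. Adgre1 and C1qa, macrophage markers, Cd3e, a marker of T cells, and Alas2 and Gata1, genes of red cell formation, had none in either library. A peak in a single library was seen at Lyz2, the myeloid lysozyme, and Tal1 in replicate 2 and at Epor, the erythropoietin receptor, in replicate 1. Of the cardiac and neuronal genes, Hand2 and Grin1 had one in replicate 2 alone. Promoters of liver genes were likewise closed, at 0 of 12 (adjusted exact p = 0.00126; Ahsg and Alb, serum proteins), as were cardiac genes at 0 of 11 (0.00155, exact; Gata4 and Hand1, heart factors). Neuronal genes had 1 of 12 (8.33%, adjusted exact p = 0.00643). That gene was Camk2a, a calmodulin kinase (2.89 and 2.56). Its peak lay at an internal start site on chromosome 18 (60963401 to 60963620 in replicate 1), in a locus whose internal promoter is known to give alphaKAP, a kinase anchoring protein of skeletal muscle. By contrast, Gad1 and Gad2, which make GABA, had none. Against random lists of the same CpG content the macrophage, lymphocyte, erythroid and liver lists did not pass (adjusted permutation p = 0.84, 0.96, 0.38 and 0.56). Those random lists had means of 10.4%, 11.4%, 17.0% and 14.2%, and more than 2.5% of them reached 0% too, so that comparison could not have called these lists lower. The cardiac call ended as well (mean 27.4%, adjusted permutation p = 0.052), whereas the neuronal share stayed below their mean of 58.5% (adjusted permutation p = 0.0020). Without replicate 1 the erythroid call was lost too (22.2%, adjusted exact p = 0.095), and with all annotated transcripts, an alternative chosen after seeing the data, the lymphocyte call (adjusted exact p = 0.059).

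Germ cell and keratinocyte genes each had 1 of 8 (12.5%, adjusted exact p = 0.0638 for both). Dazl, a germline RNA-binding protein, had values of 7.16 and 3.51 and Krt10, a skin keratin, 5.40 and 3.47, the latter from a peak inside the gene on chromosome 11 (99385921 to 99386180). Acrv1, Ddx4, Flg and Ivl had no promoter peak in either library.

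Markers of the resident non-fibre cells of muscle had open promoters at shares that did not pass the test against other genes, apart from blood cells. Satellite cell genes had promoter peaks in both animals at 7 of 12 members (58.3%, adjusted exact p = 1). Spry1, a signalling inhibitor of quiescent stem cells, had values of 7.24 and 11.3, Hey1, a Notch target, 8.24 and 4.84, Sdc4 (syndecan) 4.06 and 2.60 and Cxcr4 2.63 and 3.40. Calcr and Itga7 had none, and Pax7, the satellite cell factor, had one in replicate 2 alone. Fibro-adipogenic progenitor genes had 6 of 12 (50%, 0.838, exact), with Col1a1 and Col3a1 (fibrillar collagens) at 5.51 and 4.17 and at 2.36 and 1.83, Pdgfra at 3.05 and 3.20 and Cd34 at 3.77 and 2.22, and none at Lum and Ly6a. Tenocyte genes had 2 of 7 (28.6%, 0.431, exact). These were the tendon factors Mkx (2.44 and 2.95) and Scx (1.85 and 1.38), while Comp and Fmod had none.

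Endothelial genes had promoter peaks at 6 of 12 members (50%, adjusted exact p = 0.838), including Egfl7 (2.60 and 1.61), Esam (2.85 and 1.35), Sox18 (1.78 and 1.35) and Kdr, a VEGF receptor (2.28 and 1.27), but not Emcn or Erg. Smooth muscle and pericyte genes had 4 of 10 (40%, 0.677, exact), namely Pdgfrb (2.92 and 1.97), Myh11 (2.42 and 1.77), Kcnj8 (2.34 and 1.33) and Abcc9 (1.71 and 1.97). Acta2 and Cnn1 of that list had none. Rgs5, Notch3 and Lmod1 had one in replicate 1 alone, so without replicate 2 the list had 7 of 10 (70%). Adipocyte genes had 3 of 8 (37.5%, 0.677, exact): Cebpa (9.94 and 6.66), Lipe (4.87 and 2.87) and Pparg (0.974 and 1.30), with none at Adipoq and Cidec. Schwann cell genes had 5 of 9 (55.6%, adjusted exact p = 1). These included Prx (periaxin) at 10.5 and 7.80, Egr2 at 5.57 and 4.70 and Pmp22 at 4.19 and 3.31. Mbp and Ncmap had none. Against random lists of the same CpG content the progenitor and endothelial shares lay above means of 31.4% and 44.2% and the satellite cell share below a mean of 62.1% (adjusted permutation p = 0.38, 1 and 1). At or above the median value of their list, peaks gave shares of 33.3%, 25% and 44.4% for progenitor, endothelial and Schwann cell genes, each below other genes (adjusted exact p = 0.56, 0.29 and 1). In either library alone the progenitor and endothelial shares lay above other genes (adjusted exact p from 0.66 to 1).

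**Figure D3:**
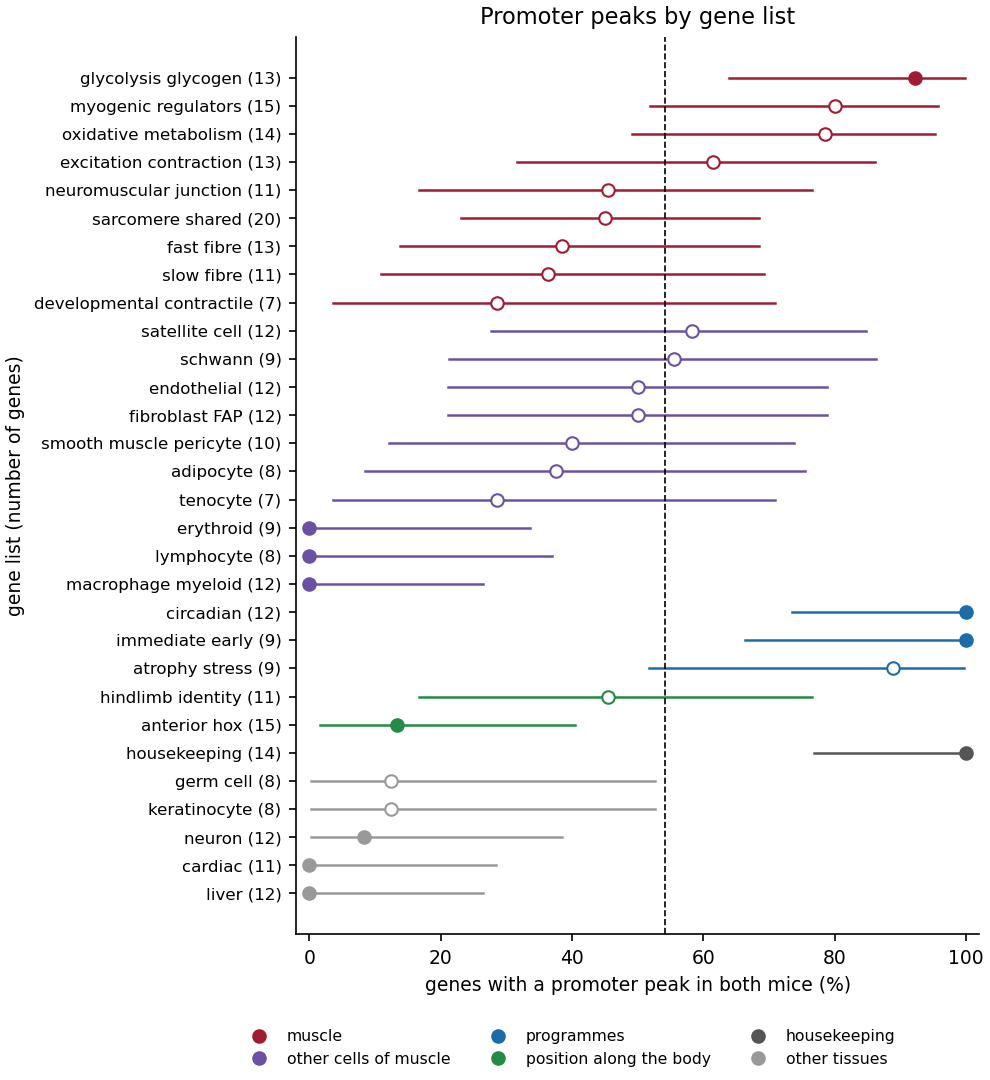
Percent of each list's genes with a promoter peak in both mice (horizontal axis) for 30 lists (vertical axis, number of genes in parentheses), with the exact 95% interval as a line, the share of all protein-coding genes (54.2%) as a dashed line, and filled points for lists whose adjusted exact p was at or below 0.05. Of the filled points, 4 lie above the dashed line, among them glycolysis and glycogen genes at 92.3%, and 7 lie below it.

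Hox genes, which mark position along the body, were open in part. Of 11 hindlimb genes 5 had a promoter peak in both animals (45.5%, adjusted exact p = 0.677), including Hoxc10 (8.09 and 5.03), Hoxa10 (5.49 and 4.80), Hoxa9 (3.59 and 3.09) and Hoxd9 (2.65 and 2.42). Pitx1 and Tbx4, the factors of hindlimb identity, had none. Among anterior Hox genes 2 of 15 had one, among them Hoxa4 (4.57 and 2.89), below other genes (13.3%, adjusted exact p = 0.00620), while Hoxa2 and Hoxb1 had none. Hoxc9, Hoxc11 and Hoxa11 of the hindlimb list were open in replicate 2 alone, and without replicate 1 its share was 72.7%, above other genes (adjusted exact p = 0.46). Hoxa3, Hoxa5, Hoxc5 and Hoxd3 had a promoter peak in replicate 2 alone, and without replicate 1 the anterior share was 40% and the call was lost (adjusted exact p = 0.30). Random lists of the same CpG content averaged 66.0%, above the anterior share (adjusted permutation p = 0.0020), and 79.6% for the hindlimb list (adjusted permutation p = 0.085).

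Open regions far from promoters gathered at some genes. Of the replicated regions, 15864 lay over 1 kb from any start site, and 7030 genes had at least 1 such region within the gene body and 10 kb either side. Gm20388 had the most, 125, but this gene model spans 119910841 to 124345722 on chromosome 8 and covers many other genes. Gse1, inside that span, had 23. Fgfr2, a growth factor receptor whose annotated span on chromosome 7 runs from 130162451 to 133123350, had 37. Maml3 (a Notch coactivator) had 18, and Arhgap26, Rora (a nuclear receptor), Sh3pxd2a and Tns1 (tensin) 16 each, followed by Nfib, a nuclear factor I gene, with 13.

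Circadian genes had a mean of 1.67 distal regions, against 0.550 for random lists matched on gene length (two-sided permutation p = 0.0034, adjusted 0.10). Immediate early genes had 1.11 against 0.297 (permutation p = 0.012, adjusted 0.14), regulators of muscle identity 2.33 against 0.887 (permutation p = 0.014, adjusted 0.14) and excitation-contraction genes 2.31 against 1.01 (permutation p = 0.022, adjusted 0.16). No list passed the adjusted threshold in either direction with the permutation test, and these 4 of 30 lists had an unadjusted permutation p under 0.05, all with more regions. Nfix, chosen after its values were seen, held 11 of the regions at muscle identity genes, Tead1 7 and Mef2d 4, and Bin1 held 6 of those at excitation-contraction genes. With peaks at or above the median value of their list, the circadian and immediate early lists passed (adjusted permutation p = 0.042 for each), as did the circadian list with the longer peak lists, added after seeing the data (2.83 regions, adjusted permutation p = 0.030). Hindlimb genes had a mean of 0.0909 regions against 0.311 (permutation p = 0.41), but without replicate 1 the mean was 3.73 against 0.566 (adjusted permutation p = 0.018). Several of these genes are neighbours in Hox clusters and can share regions, which random lists matched on length do not mimic. Over the Hoxa and Hoxc clusters most regions of replicate 2 alone lay in the packed windows described below.

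Means for the other muscle lists, each set against its length-matched random mean, were 0.538 against 0.393 for fast-fibre genes, 0.818 against 0.557 for slow-fibre genes, 0.750 against 0.788 for shared sarcomere genes, 0.692 against 0.511 for glycolysis and glycogen genes, 1.00 against 0.619 for oxidative genes, 0.857 against 0.625 for developmental contractile genes and 0.818 against 0.549 for neuromuscular junction genes. None of these passed the permutation test (adjusted p from 0.60 to 1). Without replicate 1 the gap widened for fast-fibre genes (2.85 against 0.709, permutation p = 0.0064, adjusted 0.094) and glycolysis and glycogen genes (2.31 against 0.904), and the direction turned for shared sarcomere genes (2.85 against 1.29, adjusted permutation p = 0.21 for both). The ratio to the random mean fell for slow-fibre (1.00 against 0.969), oxidative (1.36 against 1.04) and neuromuscular junction genes (1.18 against 0.940), and developmental contractile genes turned to slightly fewer (1.00 against 1.07). Without replicate 2 fast-fibre genes had 1.31 against 0.612 (adjusted permutation p = 0.20). Endothelial genes (1.67 against 0.849), smooth muscle and pericyte genes (1.40 against 0.665) and neuronal genes (1.58 against 0.799) had higher means than their random lists with adjusted permutation p = 0.31 each. Germ cell genes had a mean of 0 regions against 0.351 (adjusted permutation p = 0.55). The lists not given here had adjusted permutation p from 0.31 to 1.

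Open regions lay at gene starts far more often than shifted regions. Promoters held 47.1% of the 32662 replicated regions, 10.8 times the mean of 4.34% for shifted regions. Introns held 23.8% against 39.6% shifted, and intergenic sequence 23.6% against 50.3%. Exons held 5.49% against 5.78%, inside the range of the shifts (5.35 to 6.36%). Among all 47811 merged regions of replicate 2, shared or not, exons held 7.57%, above their shifted mean of 5.44%. Among all 50579 of replicate 1 they held 5.49% against 5.07%.

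The X chromosome held fewer open regions per Mb than any autosome. In these males, which carry a single X, 725 replicated regions lay on the X, 4.31 per Mb against 13.3 per Mb over the autosomes, a ratio of 0.325 (95% interval 0.302 to 0.350, counting error only). Autosomes ranged from 9.30 per Mb on chromosome 14 to 22.3 per Mb on chromosome 11. Among X genes 357 of 948 (37.7%, 34.6 to 40.8) had a promoter peak in both animals, against 55.4% of 20720 autosomal genes. Where present, X promoters had a median value of 3.02 in replicate 1 and 1.96 in replicate 2, against 5.87 and 4.04 for autosomal genes, ratios of 0.515 (bootstrap 95% interval 0.466 to 0.583) and 0.487 (0.435 to 0.535). The Y held 16 replicated regions.

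Footprints are short stretches inside open chromatin that are protected from cleavage, as where a protein sits on the DNA. The authors listed 155037 in replicate 1 and 234134 in replicate 2, each with a median width of 10 bp. A peak of the same library held 75.7% of them in replicate 1 and 63.6% in replicate 2, against 0.401% and 0.503% for shifted footprints. Recurrence was lower than for peaks: 52.2% of replicate 1 footprints overlapped one of replicate 2, and 33.1% of replicate 2 footprints overlapped one of replicate 1. Inside replicated regions, a setting chosen after seeing the data, these shares were 69.2% and 47.5%, against 43.3% and 31.9% for footprints placed at random within the same regions. Of the peaks, 88.7% in replicate 1 and 84.5% in replicate 2 held a footprint.

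Sites of broadly acting factors were raised in footprints, and so, slightly, was the short CAGCTG E-box. In 251878 windows of 30 bp centred on footprints of both libraries, the CTCF consensus, a boundary factor's site, occurred in 2.28% against 0.0302% of control windows from the same peaks, 75.6 times as often. NRF1 sites, which lie at promoters of housekeeping and mitochondrial genes, occurred in 0.253% against 0.00318% (79.8 times, adjusted exact p = 1.77e-176). The relaxed nuclear factor I site was found in 0.904% against 0.0457% (19.8 times), and its full palindrome in 47 windows against 0. SP and KLF sites stood at 4.54% against 0.802% (5.66 times), ETS sites at 0.551% against 0.298% (1.85 times) and YY1 sites at 0.0909% against 0.0528% (1.72 times). The short CAGCTG E-box, searched for MyoD family factors, stood at 3.15% against 2.69% (1.17 times, adjusted exact p = 5.17e-22, Benjamini-Hochberg over 21 motifs). Its longer form was not raised, as given below, and windows were not matched on base composition, for this or any other motif. The rise of the short E-box is thus not shown to be that of a muscle factor. The ratio of this E-box was 1.33 in peaks over 1 kb from a start site and 1.55 in footprints as called (adjusted exact p = 4.68e-44 and 7.11e-58). Several ratios of the other sites rest on few control sites and moved with the setting. In peaks over 1 kb from a start site NRF1 stood at 21.7 (65 windows against 3) and the relaxed nuclear factor I site at 32.2. In footprints as called CTCF stood at 337 (4379 windows against 13), relaxed nuclear factor I at 340 (1360 against 4), SP and KLF at 13.9 and NRF1 at 590 windows against 0.

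The longer E-box and the MEF2 and SRF motifs were not raised in footprints. The longer E-box had a ratio of 0.891 (adjusted exact p = 0.0592) and SRF 0.986 (0.97, exact). In footprints as called, with windows of the same width, they and MEF2 lay below controls, at 0.642 for the longer E-box and 0.441 for SRF (adjusted exact p = 7.03e-04 for each) and 0.360 for MEF2 (adjusted exact p = 2.29e-04). In 30 bp windows MEF2 sites had a ratio of 0.997 in both libraries together (adjusted exact p = 1). Taken apart, MEF2 was at 1.27 in replicate 1 (adjusted exact p = 0.0637) and lower than controls in replicate 2, at 0.696 (adjusted exact p = 0.0108). Sites of TEAD (0.844), RUNX (0.736), glucocorticoid receptor (0.680), PU.1 (0.598), the nuclear receptor site of the ESRR family (0.566) and GATA (0.548) were fewer in footprints than in controls (adjusted exact p from 6.65e-07 to 0.0247). Of these 6, TEAD remained below with replicate 1 alone and in peaks over 1 kb from a start site, and the other 5 calls were lost in both settings, with the glucocorticoid receptor call also lost with replicate 2 alone. AP-1 had a ratio of 1.04 (adjusted exact p = 0.292) but passed as higher in peaks over 1 kb from a start site (1.14, adjusted exact p = 0.00331), with replicate 1 alone (1.12, adjusted exact p = 0.0336), and as lower in footprints as called (0.669, adjusted exact p = 9.08e-08). With replicate 2 alone the AP-1 ratio turned to 0.942 (adjusted exact p = 0.304). HNF4, a liver site, had 1.17 (adjusted exact p = 0.532), but 1.96 in peaks over 1 kb from a start site (adjusted exact p = 0.0199). In footprints as called its ratio turned to 0.714 (10 windows against 14, adjusted exact p = 0.568). REST sites were found in 5 windows against 0 (adjusted exact p = 0.0820). ETS lost its call in peaks over 1 kb from a start site, where few sites were left (1.43, 86 windows against 60, adjusted exact p = 0.0800). YY1 lost its call there too (3.33, 10 windows against 3, adjusted exact p = 0.138), as well as with replicate 1 alone (1.05) and in footprints as called (1.00). A site shared by both libraries entered once per library, so these windows are not independent. Windows were not matched on base composition or on place within the peak. Neither a rise nor a fall of a motif therefore shows by itself that its factor was bound or absent.

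**Figure D4:**
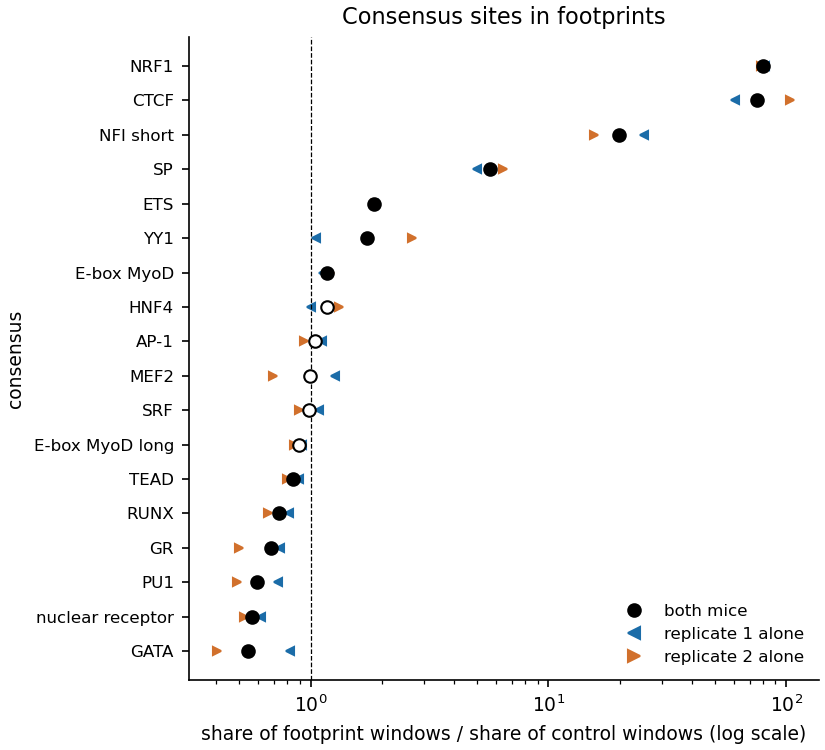
Ratio of the share of footprint windows with each consensus to the share of control windows (horizontal axis, log scale) for 18 consensus sequences (vertical axis), as circles for both mice together, filled where the adjusted exact p was at or below 0.05, and triangles for each replicate alone, with a dashed line at a ratio of 1. CTCF lies at 75.6 and NRF1 at 79.8, while MEF2 lies at 0.997; the NFI palindrome and REST had no control site and are not drawn.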

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

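Some bases outside the peaks had deposited q-values at the limit of the shorter lists. At a q-value at or below 0.001, 4.61 Mb of replicate 1 and 7.13 Mb of replicate 2 lay outside the shorter peak lists, of 13.6 Mb and 18.2 Mb in all. These bases are signal in a file that none of the comparisons above used. The peaks thus held 66.1% and 60.8% of the bases at that limit. Whether the other bases flank called peaks or lie at promoters without a peak was not measured. Cleavage above background at such promoters therefore stays possible. This was looked at as a measured value, and no explanation was tested.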

How the results depend on the processing

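Depth in reads is unknown and the group has 2 animals, so single-library values are the only check on spread. Of 70 alternatives to the main values, 25 stayed within their limits and 45 moved; of 657 for single lists, genes and motifs, 491 kept direction and side of the threshold or stayed within the spread, 60 without a call in either setting turned direction (23 for promoter lists, 30 for distal lists, 7 for motifs), 26 lost a call, 14 gained one, 64 promoter percentiles moved and 2 turned with a call. Unless construction shows it, the cause was not tested.

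Shared peaks were 50.2% and 51.8% (replicate 1 and 2) at 50% reciprocal overlap, 79.9% and 80.8% at or above the median value, 69.2% and 67.5% with equal numbers of peaks and 66.0% and 63.8% with the longer lists. Spearman's correlation was 0.87 with reciprocal overlap and 0.81 above the median value, where weak pairs are left out. With each list split into 5 parts by value, recurrence of the strongest exceeded that of the weakest by 62 and 76.1 points with reciprocal overlap and by 67.5 and 87.9 with the longer lists (64.7 and 86.3 in the main lists).

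Genes with a promoter peak came to 55.5% at 1000 bp, 49.4% at 100 bp, 47.5% at or above the median value, 59.0% with the longer lists, 55.7% with all transcripts (chosen after seeing the data) and 55.8 to 57.1% without a replicate. Random lists of the same CpG content left 2 lists above and 2 below, where the main test had 4 and 7; 7 lists at 0% or 100% could not pass there, since random lists reached these shares too. For distal regions, 2 lists passed at or above the median value, 1 with the longer lists (chosen after seeing the data) and 0 to 1 without a replicate; hindlimb genes turned from fewer to more regions without replicate 1 (means of 0.182 to 3.73 without a replicate).

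Promoter regions were 51.4% at 1000 bp, 61.5% at or above the median value and 38.0 to 40.4% without a replicate; intergenic regions were 22.5%, 17.1% and 24.9 to 26.4%. The X to autosome ratio was 0.234 at or above the median value and 0.246 over 1 kb from a TSS.

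Footprints inside a peak were 74.2% and 62.3% with at least 50% of the footprint required inside and 92.9% and 84.6% with the longer lists; 69.2% and 47.5% were shared inside replicated regions (the latter pair of settings chosen after seeing the data). Each footprint value is already that of a single library. Ranking footprints by value was not run, since the value is constant. Motifs below controls were 11 in footprints as called, 1 over 1 kb from a TSS and 1 to 6 without a replicate, against 6 in the main test. AP-1 turned to fewer sites in footprints as called, by -0.0599 percentage points.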

Other observations

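Gene families, chosen after their values were seen, differed in how many promoters were open, without matching on CpG content. A promoter peak in both animals was found at 74 of 76 ribosomal protein genes (97.4%), 45 of 46 NADH dehydrogenase subunit genes (97.8%), 37 of 40 proteasome genes (92.5%), 297 of 365 zinc finger Zfp genes (81.4%), 14 of 17 Klf genes (82.4%) and 47 of 67 canonical histone genes (70.1%), each above other genes (Fisher's exact test, two-sided, adjusted p over 20 families from 4.76e-27 to 0.0325). Olfactory receptors had 1 of 1134, vomeronasal receptors 1 of 331, beta-defensins 0 of 42, kallikreins 0 of 27, keratins 2 of 49, serpins 8 of 61 (13.1%), cytochrome P450 genes 14 of 93 (15.1%), Wnt ligands 3 of 19 (15.8%), Hox factors 9 of 39 (23.1%) and potassium channels 30 of 94 (31.9%). These 10 families lay below other genes, with adjusted exact p of at most 0.00117. Collagens (23 of 44), Sox factors (10 of 19), Fox factors (19 of 44) and integrins (15 of 24) did not pass (adjusted exact p from 0.203 to 1).

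Peak counts over the Hox clusters differed between the animals. Replicate 2 had 44 peaks over the Hoxa cluster on chromosome 6 where replicate 1 had 10, and 31 against 7 over the Hoxc cluster on chromosome 15 (102921103 to 103036852). Of the regions of replicate 2 alone, 30 of 34 over Hoxa and 22 of 25 over Hoxc lay in the packed windows described below, though with median values of 1.08 and 1.17. The counts were 7 against 4 over Hoxd and 6 against 2 over Hoxb. Around Hoxc10, 12 distal peaks in replicate 2 stood against 0 in replicate 1. Nr1d1 (15 against 2), Cdkn1a (9 against 0), Bin1 (29 against 12) and Tns1 (47 against 30) also had more in replicate 2, and Gse1 (25 against 33) and Rora (24 against 30) had fewer. Over all genes, 4469 had more distal peaks in replicate 1 and 2394 in replicate 2, and gaps of at least 5 peaks were seen at 173 and 381. Each of these genes was picked after its counts were seen.

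For the packing of weak peaks, the test of a varying threshold was chosen after the result was seen, as was that of a single X copy for X promoter values; the other tests were written before. For the packing no biological explanation was tested, since both animals belong to 1 group, and a true difference between them stays open.

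Weak peaks of replicate 2 lay packed in short stretches. Of its 14957 regions absent from replicate 1, 6430 (43.0%) lay in 628 windows of 50 kb with 5 or more of them, against 2.55% of the 16230 regions of replicate 1 alone. The densest held 48, on chromosome 17 at 31850001 to 31900000 beside Sik1. Other dense windows lay next to the 3 Mb assembly gap, without a protein-coding gene and with 0 replicate 1 peaks. These were at 3000001 to 3050000 on chromosomes 17 (46 regions) and 3 (34), and at 3050001 to 3100000 on chromosome 4 (37). Errors of read mapping were not tested as a cause. A lower threshold from greater depth stays open. Weaker replicate 1 peaks, thinned to the same number, had 0.811% in such windows, below the share predicted for this cause. That value cannot decide the question, since thinning itself breaks up packed windows and a looser limit does not stand for greater depth. Without thinning, the 33079 regions that only the longer list of replicate 1 holds had 7.18% there, against 16.5% for the 35550 such regions of replicate 2. A bias of replicate 2 towards higher GC content predicted a higher median GC content in the packed regions. Their median was instead lower than that of the other regions of replicate 2 alone, by a difference of -2.98 points (-3.34 to -2.62). Higher GC content thus did not set the packed regions apart. Both sets come from replicate 2, so a GC bias of that whole library cannot be decided. Medians were 53.8% in packed and 56.7% in other regions, 53.0% in regions of replicate 1 alone and 58.6% in regions of both. The test asked only about higher GC content, so a bias towards lower GC content stays open. A calling threshold that varies along the genome stays open and cannot be told apart from other causes: the packed regions had a median value of 0.276, below the 5th percentile of 0.526 for replicate 2 peaks outside such windows, but low values are part of the pattern itself.

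X promoters had lower values than autosomal ones. With autosomal genes matched on CpG content the ratio was 0.606 in replicate 1 (0.546 to 0.681) and 0.555 in replicate 2 (0.505 to 0.602), so CpG content as the whole cause is argued against. The unmatched ratios of 0.515 and 0.487 had intervals that include 0.5, the value for a single X copy. The matched ranges lie above 0.5, but they vary the autosomal draw only and leave out the sampling error of the X genes. They therefore cannot decide whether 0.5 is excluded. Since weak X promoters without a called peak do not enter, a single copy may or may not account for the lower values and cannot be told apart from other causes.

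X genes also had promoter peaks less often, at 37.7%. Halved values falling under the calling limit stay open as a cause. Halving the values of autosomal genes left 51.7% of them at or above limits of 0.727 in replicate 1 and 0.204 in replicate 2. With the replicate 2 limit taken outside packed windows, 51.1% were left. Both shares lie over the X share. However, peaks were called by q-value, and called peaks had values down to 0.0986 in replicate 1 and 0.0591 in replicate 2. These limits are thus not the calling limit, and the test cannot say which halved promoters would go uncalled. Among autosomal genes matched on CpG content, 42.4% (40.1 to 44.5) had a promoter peak, against 55.4% of all autosomal genes. The lower CpG content of X promoters may therefore account for most of the gap, as a hypothesis from these libraries alone.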
